A study of Homo sapiens with 4 samples.

How the data were processed

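RNA from 22Rv1 cells, an established human prostate cancer cell line, was measured on 4 Illumina bead arrays. Cells had been treated for 16 h with vehicle (2 arrays) or with 10 µg/mL of WCE, a herbal extract (2 arrays), per the labels. Total RNA was extracted with a column kit and amplified to biotinylated cRNA, per the labels' protocols. The labels number the arrays within each group but do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

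The deposited raw intensities are linear scanner signals, neither background-subtracted nor normalized between arrays, as far as their values show. A detection p-value was deposited beside each signal, per the file headers, and gives the share of negative control beads at least as bright as the probe. The authors also deposited processed log2 values. Their normalization is not given in the sources used here. In each of the 4 columns the ranks equalled those of the raw signals of the same array (Spearman's rho 1 across probes), and the values lay within 0.136 of quantile-normalized log2 raw signals without background correction. The column medians were 6.40 on each array. Their scale is therefore log2 and genes were not centred. The scanner software and slide are not given in the sources used here.

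The raw signals were corrected and normalized in limma 3.58.1 under R 4.3.3. Background was corrected with normexp, with the mean and SD of the negative controls inferred from the detection p-values and an offset of 16, followed by quantile normalization and log2. A larger offset, or no correction, gave smaller fold changes for dim genes such as DPYD and CXCL13. Of 47320 probes, 30112 had 1 gene symbol in the platform annotation, 8 had several and 17200 had none. Probes with several symbols were left unnamed. Symbols were looked up by gene number in a RefSeq gene table of assembly GRCh38.p14, and 0 needed updating. Some genes of the lists had no named probe here, and those are not analysed here. Of 472 list genes, 443 had a probe and 373 were tested.

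A probe was kept when its detection p-value was below 0.05 on both arrays of at least 1 group, which left 21996 probes, 16447 of them named. The brightest kept probe stood for its gene, giving 12136 tested genes. Among the genes past the threshold, 61 had several tested probes, 4 of these had a probe of the opposite sign and 0 had one past the threshold. WCE was compared with vehicle by lmFit and eBayes, with Benjamini-Hochberg adjustment at 0.05 over all genes. The fit had 2 residual and 7.12 prior degrees of freedom. A 2-against-2 design cannot give a two-sided exact permutation p below 0.333, so calls for single genes rest on limma's pooled variance. Fold changes are WCE relative to vehicle, given as log2 with the standard error of the fit. Where a gene was detected on no array of a group, the fold is a lower bound, which holds only with this background correction. The bound sets the bright group's mean against the mean, over the dim arrays, of the higher of the probe's own value and the lowest signal among detected probes.

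Before the data were examined, 26 gene lists and the genes to be named were fixed. The rule took the 12 largest rises and 12 largest falls past the threshold with non-overlapping groups, skipping uncharacterised symbols, up to 4 members of each list with the smallest p, and a few genes whatever their values. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists tested. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance 1 way, were alternatives. With an estimated correlation camera refers its statistic to the 2 residual degrees of freedom, which raises its p-values.

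The steps were tested on simulated data. In 10 simulated versions of the WCE comparison, with 200 changed genes each among on average 12859 tested, 1.21% of the genes changed 1.5-fold were recovered, 13.8% of those changed 2-fold and 86.6% of those changed 4-fold. Of the calls, 3.23% were false. A list of 20 genes shifted by 0.5 on the log2 scale had p below 0.05 in 100% of the sets with the preset correlation and in 90% with an estimated one. Noise was drawn independently for each probe, with the same spread in both groups. These rates therefore do not cover correlated genes, or WCE arrays that lie farther apart than the vehicle arrays. Most simulated 2-fold changes went uncalled. The number of arrays limits the precision.

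Other choices tried were no background correction, an offset of 50, median scaling, cyclic loess, the authors' processed values, no detection filter, a strict filter (detection p below 0.01 on all 4 arrays), the mean of a gene's probes, a trended robust variance, fold thresholds, a replicate block and leaving out each array. Leaving out an array leaves 1 array in its group, which is then assumed to vary like the 2 arrays of the other group.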

Results

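Gene expression was measured in 22Rv1 prostate cancer cells after 16 h with vehicle or with 10 µg/mL of WCE, a herbal extract, with 2 arrays in each group. The comparison asks which transcripts the extract changes in these cells. Median raw signals were 83.5 and 82.95 on the vehicle arrays and 85.1 and 81.7 on the WCE arrays. Between 45.2% and 48.9% of probes were detected on each array. The vehicle arrays correlated across probes at r = 0.993 and the WCE arrays at r = 0.989, and 51 and 304 probes differed over 2-fold within these pairs.

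The largest rises after WCE were those of 3 cytochromes, CYP1A1, CYP1A2 and CYP1B1. CYP1A1 (probe ILMN_1807291), which oxidises aromatic hydrocarbons, rose 97.8-fold, from a log2 signal of 5.91 ± 0.20 to 12.52 ± 0.18 (SD, n = 2 per group). CYP1A2, detected on 1 of the 2 vehicle arrays, rose 46.6-fold and CYP1B1 23.7-fold. The sizes of these 3 rises depended on the background correction, without which they were 52.5-fold, 19.1-fold and 14.0-fold. GDF15, a stress-induced secreted factor of the TGF-beta family, rose 13.8-fold. The largest fall was that of PMEPA1, an androgen-induced gene that restrains TGF-beta signalling, at 4.78-fold, from 11.02 ± 0.09 to 8.76 ± 0.14 (SD, n = 2 per group). In total 229 of 12136 genes passed limma's adjusted p of 0.05, of which 143 were higher and 86 lower after WCE, and 124 of them changed at least 2-fold. All 229 had non-overlapping groups, as did 50.3% of all tested genes against 33.3% by chance. The count depended on single arrays: it was 75 without vehicle replicate 1, 77 without vehicle replicate 2, 860 without WCE replicate 1 and 123 without WCE replicate 2. In each of these fits the lone array of a group is assumed to vary like the other group, so without a WCE array the spread is that of the vehicle arrays, which lay closer together. That spread enters both fits without a WCE array, so it does not explain why their counts differ. Without a detection filter the count was 53, and with median scaling 132, of which 102 were higher and 30 lower. Of the 49 called genes named here, 20 did not pass without a filter and 9 with median scaling. They were SPATA13, DDC, DAPL1, ANKRD20A1, HMOX1, CDKN1A, UGT2B15, SESN2, HYOU1, DNAJB9, ME1, IFITM1, FOSB, BMF, WIPI1, NEU1, GABARAPL1, MT1F, MT1M and KRT19 without a filter, and SPATA13, ANKRD20A1, UGT2B15, DNAJB9, ME1, IFITM1, GABARAPL1, MT1M and KRT19 with median scaling. With cyclic loess ANKRD20A1, DNAJB9, NEU1 and GABARAPL1 did not pass. At the level of probes 186 passed, 117 higher and 69 lower, and 29 of these have no gene name here.

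**Figure D1:**
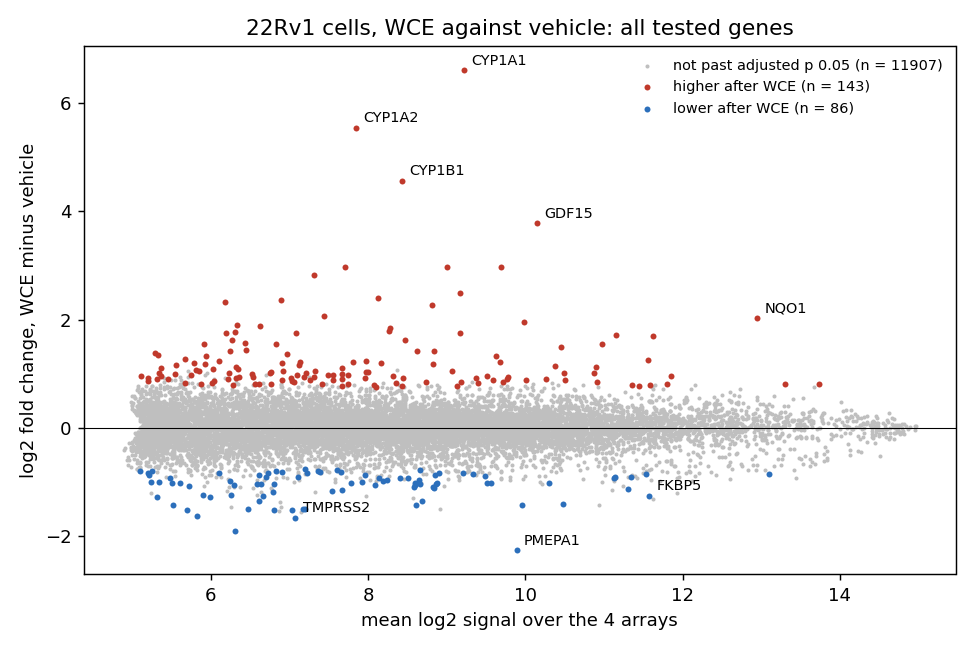
Each point is 1 of the 12136 tested genes, with the mean log2 signal over the 4 arrays on the x axis and the log2 fold change of WCE minus vehicle on the y axis. Red and blue points are the 143 higher and 86 lower genes past limma's adjusted p of 0.05, and CYP1A1 lies highest at 6.61.

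Beyond these 4, the largest rises were those of FST, a secreted activin antagonist (log2 fold change 2.98 ± 0.22, SE), TIPARP, an ADP-ribosyltransferase induced through the aryl hydrocarbon receptor (2.97 ± 0.19), and CGA, the common subunit of glycoprotein hormones (2.97 ± 0.19). UGT1A1, which conjugates bilirubin and drugs, followed at 2.82 ± 0.16, then the pyruvate dehydrogenase kinase PDK4 at 2.49 ± 0.24, TCIM at 2.40 ± 0.21, the cadherin CDH12 at 2.36 ± 0.16 and the drug efflux pump ABCG2 at 2.32 ± 0.21. UGT1A1 shares its last exons with other UGT1A genes. The probes assigned to UGT1A3 and UGT1A6 had log2 fold changes of 0.27 and 0.26 and did not pass. That of UGT1A6 was detected on 1 of the 2 vehicle arrays. ABCG2 was detected on 1 of the 2 vehicle arrays, and without background correction it had 1.37.

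After PMEPA1, the largest falls were those of SPATA13 (-1.90 ± 0.32, SE) and the androgen-induced membrane protease TMPRSS2 (-1.66 ± 0.17). DPYD, which degrades pyrimidines, was not detected on either WCE array and fell at least 2.83-fold (adjusted p = 0.00275, limma). As this is a bound, its rank among the falls is not known. CXCL13, a B-cell chemokine, was likewise undetected after WCE and fell at least 2.14-fold (adjusted p = 0.00335, limma). CYP2C8, the thyroid hormone-binding CRYM, the potassium channel KCNMA1, PTPRB, the decarboxylase DDC and DAPL1 fell by between 1.49 and 1.52 on the log2 scale. CYP2C8 was detected on 1 WCE array. ANKRD20A1, of a multi-copy family whose members a probe may not separate, had -1.42 ± 0.29. Its WCE arrays were far apart (SD 0.73), as were those of SPATA13 (SD 0.83), which was detected on 1 WCE array. The call of ANKRD20A1 was lost without vehicle replicate 1 (adjusted p = 0.121), vehicle replicate 2 (0.117) or WCE replicate 2 (0.066, with a log2 fold change of -0.91), and under median scaling, cyclic loess, no filter and a trended variance. SPATA13 did not pass under median scaling (0.0682) or without a filter (0.137). Without background correction SPATA13, DPYD, CYP2C8, DAPL1 and CXCL13 had smaller changes, at -1.15, -0.88, -0.80, -0.93 and -0.74.

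**Figure D2:**
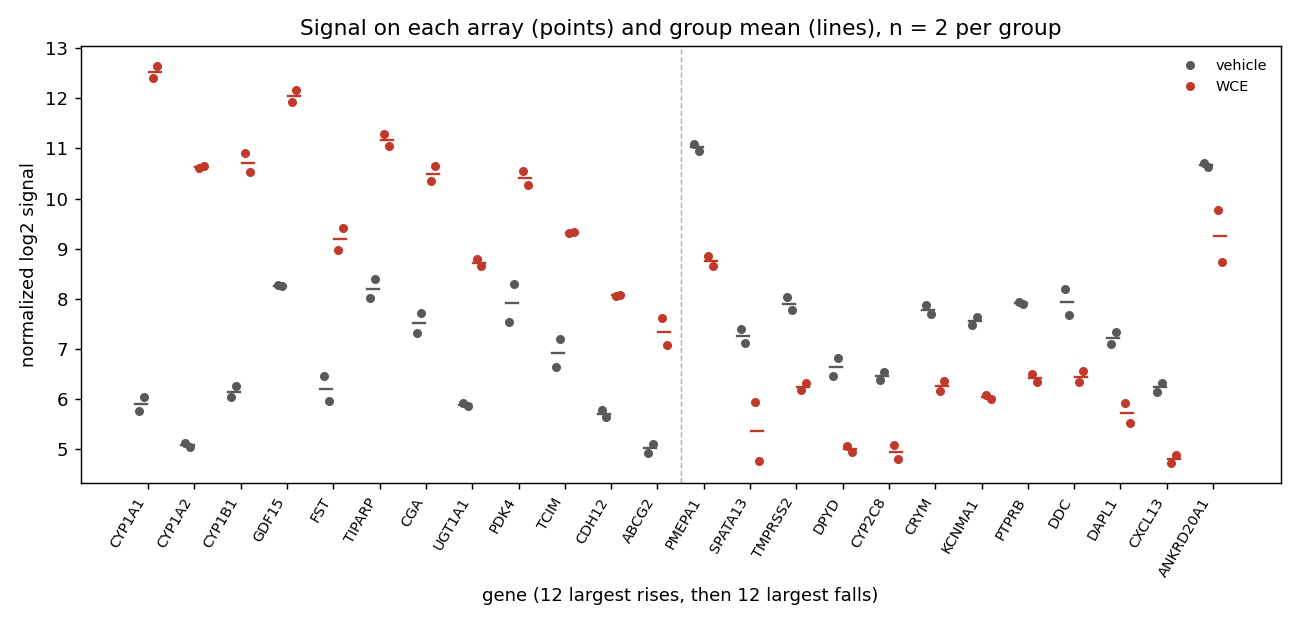
Points are the normalized log2 signals of the 2 vehicle (grey) and 2 WCE (red) arrays and short lines the group means, for the 12 largest rises and then the 12 largest falls. The groups do not overlap for any of these genes, and the WCE arrays of SPATA13 and ANKRD20A1 are the farthest apart.

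Targets of the aryl hydrocarbon receptor, a ligand-activated sensor of aromatic compounds, formed the most strongly raised list. Of 7 measured members 5 rose, both over all genes and adjusted over the list alone, with a median log2 fold change of 2.97. They were CYP1A1, CYP1A2, CYP1B1, TIPARP and NQO1. The list passed camera (adjusted p = 1.98e-14), and its adjusted p was 0.205 with an estimated correlation. Without a detection filter its median was 1.202.

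Androgen-induced genes fell as a list. Of 22 measured members 7 fell and 1 rose, or 11 and 2 adjusted over the list alone, with a median log2 fold change of -0.47 (camera adjusted p = 1.3e-07). The adjusted p was 0.205 with an estimated correlation. PMEPA1, TMPRSS2 and the steroid receptor co-chaperone FKBP5 (-1.25 ± 0.17, SE) led the falls, and the prostaglandin receptor PTGER4 rose (1.22 ± 0.17). Without vehicle replicate 2 the calls of FKBP5 (adjusted p = 0.0704, limma) and PTGER4 (0.056) were lost. KLK3, which encodes prostate-specific antigen, was not detected well enough to be tested. Among 4 measured androgen-repressed genes, too few for a list test, 1 fell, the androgen-glucuronidating enzyme UGT2B15 (-0.96 ± 0.16). UGT2B17, MET and CCN3 had -0.76, 0.42 and 0.31 without passing over all genes. Adjusted over the list alone, 1 was higher, MET, and 2 were lower, UGT2B15 and UGT2B17. Which of these 2 passed over all genes depended on the probe. The second probe of UGT2B17 had -0.98 (adjusted p = 0.0406 over all probes, limma), and that of UGT2B15 had -0.72 (0.108). Androgen synthesis and inactivation genes did not pass as a list (8 measured, median -0.04, camera adjusted p = 0.0965). UGT2B15 alone was lower over all genes, and 2 members were lower adjusted over the list alone. SRD5A1 and AKR1C3 had -0.19 and -0.12, and with median scaling AKR1C3 had 0.01. UGT2B15 and UGT2B17 are near-identical in sequence, so their probes may not separate them, and UGT2B15 lost its call without vehicle replicate 1 (adjusted p = 0.155), vehicle replicate 2 (0.11) or WCE replicate 2 (0.0721).

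Genes of the oxidative stress response governed by NRF2 rose. Of 22 measured, 9 rose and 0 fell, or 15 and 0 adjusted over the list alone, with a median of 0.70 (camera adjusted p = 1.13e-10). The adjusted p was 0.22 with an estimated correlation. The quinone reductase NQO1 rose by 2.03 ± 0.16 (log2, SE), the glutathione peroxidase GPX2 by 2.06 ± 0.20, the aldo-keto reductase AKR1C2 by 1.54 ± 0.16 and the haem oxygenase HMOX1 by 1.75 ± 0.21. AKR1C2 belongs to a family of close paralogs. HMOX1 did not pass without a detection filter (adjusted p = 0.0588, limma). Metallothioneins, which bind zinc and copper, also rose as a list (8 measured, 2 higher, 5 adjusted over the list alone, median 0.58, camera adjusted p = 6.23e-05), with an adjusted p of 0.325 with an estimated correlation. MT1F (0.88 ± 0.16) and MT1M (0.81 ± 0.16), near-identical family members, passed over all genes, and the zinc exporter SLC30A1 had 0.76 and MT1G 0.57. A second probe of SLC30A1 had 0.96 (adjusted p = 0.0434 over all probes, limma). Neither MT1F nor MT1M passed without vehicle replicate 1 (adjusted p = 0.144 and 0.242), vehicle replicate 2 (0.185 and 0.181) or WCE replicate 2 (0.0877 and 0.0966).

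Endoplasmic reticulum chaperones rose as a list. Of 16 measured, 2 rose, or 11 adjusted over the list alone, with a median of 0.53 (camera adjusted p = 2.62e-08). The adjusted p was 0.205 with an estimated correlation. HYOU1 (0.91 ± 0.16, SE) and DNAJB9 (0.95 ± 0.19) passed, and the main chaperone HSPA5 (0.82 ± 0.17, adjusted p = 0.0509, limma) and EDEM1 (0.71 ± 0.16) lay just beyond the threshold. Both passed in 7 of the other settings, among them no background correction (adjusted p = 0.0154 and 0.02). Targets of ATF4, the transcription factor of the integrated stress response, rose as well. Of 22 measured, 1 rose and 0 fell, or 12 and 1 adjusted over the list alone, with a median of 0.44 (camera adjusted p = 6.38e-06). The adjusted p was 0.22 with an estimated correlation. The member that passed was SESN2 (1.07 ± 0.17), while VLDLR had 0.95, ATF3 0.74 and DDIT3 0.56. CHAC1 was undetected on both vehicle arrays, with a bound of at least 1.47-fold, and did not pass. Calls of HYOU1 and DNAJB9 were lost without vehicle replicate 1 (adjusted p = 0.161 and 0.23) or vehicle replicate 2 (both 0.16), that of HYOU1 also without WCE replicate 2 (0.0908) and that of DNAJB9 without WCE replicate 1 (0.0514), with median scaling (0.0754) and with cyclic loess (0.0647), while SESN2 was lost without vehicle replicate 1 (0.15). Heat shock genes did not pass as a list (14 measured, 0 past the threshold, median 0.05, camera adjusted p = 0.539). HSPH1, HSPA8, DNAJA1 and HSP90AA1 had 0.52, 0.30, 0.25 and 0.20.

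Immediate early genes and feedback regulators of MAPK signalling rose. Of 21 measured, 7 rose and 0 fell, or 14 and 0 adjusted over the list alone, with a median of 0.59 (camera adjusted p = 1.05e-08). The adjusted p was 0.22 with an estimated correlation. They included the transcription factors ETV5 (1.62 ± 0.16, SE), EGR1 (1.24 ± 0.16) and FOSB (0.88 ± 0.16), and the MAPK phosphatase DUSP4 (1.42 ± 0.16). FOSB lost its call without vehicle replicate 1 (adjusted p = 0.121), vehicle replicate 2 (0.192) or WCE replicate 2 (0.0845).

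Proliferation genes were lower as lists, with no single member past the threshold in the main setting. Genes of DNA replication and the G1/S transition had a median of -0.29 over 29 measured (camera adjusted p = 1.08e-05), with 25 of the 29 lower, and an adjusted p of 0.216 with an estimated correlation. POLA1, MCM4 and UHRF1 had -0.65, -0.61 and -0.56, and E2F1 had 0.54. The first 3 passed without background correction (adjusted p = 0.0436, 0.0404 and 0.0433), with the authors' processed values and with a trended variance. Genes of G2/M and mitosis had a median of -0.19 over 30 measured (camera adjusted p = 0.00124), with 27 of the 30 lower, and an adjusted p of 0.24 with an estimated correlation. NUSAP1, MKI67, KIF20A and CENPE had -0.50, -0.52, -0.41 and -0.41. Adjusted over the list alone, 0 members of either list passed. With median scaling the medians were -0.19 and -0.08, and both lists passed. Targets of p53 were higher as a list (20 measured, 2 higher, 5 adjusted over the list alone, median 0.24, camera adjusted p = 0.00124), with an adjusted p of 0.22 with an estimated correlation. The members that passed were GDF15 and the cyclin-dependent kinase inhibitor CDKN1A (0.96 ± 0.17, SE), while PHLDA3 had 0.68 and BBC3 0.57. CDKN1A lost its call without vehicle replicate 1 (adjusted p = 0.128), vehicle replicate 2 (0.155) or WCE replicate 2 (0.0867), and with the mean of its probes (0.0741).

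Cholesterol synthesis genes were higher as a list (20 measured, median 0.32, camera adjusted p = 0.00934), with an adjusted p of 0.24 with an estimated correlation. No member passed over all genes, and adjusted over the list alone 7 were higher and 2 lower. MVD and the cholesterol carrier STARD4 had 0.75 and 0.65, and HSD17B7 and PMVK had -0.79 and -0.56. Without WCE replicate 2 MVD and HSD17B7 had 0.43 and -0.42. The list did not pass without vehicle replicate 2 (adjusted p = 0.0553) or WCE replicate 2 (0.0625). Fatty acid synthesis did not pass (13 measured, median 0.10, camera adjusted p = 0.106). Its malic enzyme ME1, which is also in the NRF2 list, was higher (0.82 ± 0.16, SE). SREBF1, MID1IP1 and ACSS2 had 0.44, 0.38 and 0.24. With median scaling the fatty acid list passed (0.0391). ME1 lost its call without vehicle replicate 1 (adjusted p = 0.242), vehicle replicate 2 (0.165) or WCE replicate 2 (0.089). Hypoxia and glycolysis genes did not pass (19 measured, median 0.22, camera adjusted p = 0.0585), and KDM3A, PFKFB4, P4HA1 and ANKRD37 had 0.54, 0.45, 0.40 and 0.34. The hypoxia list passed in 6 of the alternatives, among them no background correction (adjusted p = 0.0307).

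Genes of the BCL2 family and inhibitors of apoptosis were higher as a list (15 measured, 1 higher, 2 adjusted over the list alone, median 0.18, camera adjusted p = 0.0259), with an adjusted p of 0.357 with an estimated correlation. The member that passed was BMF, which promotes apoptosis. It was undetected on both vehicle arrays and rose at least 2.35-fold (adjusted p = 0.0129, limma). BAK1 had 0.45, and HRK, undetected with vehicle, had a bound of at least 1.16-fold. Autophagy and lysosome genes were higher (19 measured, 3 higher, 5 higher and 1 lower adjusted over the list alone, median 0.12, camera adjusted p = 0.0429), with an adjusted p of 0.438 with an estimated correlation. This list did not pass camera with the replicate block (adjusted p = 0.0569). WIPI1, NEU1 and GABARAPL1 rose by 0.88 ± 0.17, 0.90 ± 0.19 and 0.76 ± 0.16 (log2, SE), and the protease CTSB had -0.66. Neither list passed without vehicle replicate 2 (both adjusted p = 0.139) or WCE replicate 2 (0.18 and 0.242), and the apoptosis list did not pass with the strict filter (0.135). Their medians were 0.30 and 0.24 with median scaling, and between 0.11 and 0.36 and between 0.05 and 0.28 with 1 array left out. BMF lost its call without vehicle replicate 2 (0.056), and the 3 autophagy genes lost theirs without either vehicle replicate or WCE replicate 2 (adjusted p from 0.104 to 0.27). GABARAPL1 did not pass with median scaling (0.0546) or cyclic loess (0.0611), nor NEU1 with cyclic loess (0.057).

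Inflammatory and interferon genes did not pass as lists. Of 10 measured NF-kB targets and cytokines 1 rose, the prostaglandin synthase PTGS2 (1.76 ± 0.20, SE), while NFKBIA, NFKB2 and IKBKE had -0.81, 0.76 and -0.52. Adjusted over the list alone, 3 members were higher and 2 lower. The list's median was -0.12 and its mean 0.10 (camera adjusted p = 0.971, direction down, while fry's was up). Of 15 interferon-stimulated genes 1 fell, IFITM1 (-0.82 ± 0.16), with a median of -0.11 (camera adjusted p = 0.178). IRF7, USP18 and IRF9 had -0.54, -0.29 and 0.26. IFITM1 did not pass under 5 of the 10 other settings, nor without vehicle replicate 1 (adjusted p = 0.246), vehicle replicate 2 (0.165) or WCE replicate 2 (0.0867). Ribosome biogenesis genes did not pass (18 measured, 0 past the threshold, median -0.12, camera adjusted p = 0.241), and NOP56, RRP9, UTP20 and NPM1 had -0.62, -0.53, 0.49 and 0.44.

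Cell identity markers did not pass as lists. Of 10 luminal epithelial markers 1 fell, the keratin KRT19 (-1.12 ± 0.22, SE), with a median of -0.15 (camera adjusted p = 0.0794). CLDN3, KRT18 and KRT8 had -0.34, -0.32 and -0.26. The luminal list passed in 5 of the alternatives, among them no background correction (adjusted p = 0.0442). KRT19 lost its call without vehicle replicate 1 (adjusted p = 0.146) or vehicle replicate 2 (0.13), with median scaling (0.0748) and without a filter (0.136). Of the basal markers only LAMB3 was measured, at 0.57 without passing. Neuroendocrine markers did not pass (9 measured, median 0.17, camera adjusted p = 0.241), with CHGB at 0.94, SYP at 0.61, SCG3 at 0.42 and SCG2 at -0.44. Mesenchymal and stromal markers did not pass (7 measured, median 0.34, camera adjusted p = 0.392), with ACTA2 at 0.66, TWIST1 at 0.61, LUM at 0.51 and CDH2 at -0.56. With 1 array left out the list's median lay between 0.06 and 0.27, and LUM between 0.06 and 0.97. Leukocyte markers did not pass (5 measured, median 0.01, mean -0.12, camera adjusted p = 0.381, direction down), with CD68, CD14, LYZ and CD2 at -0.69, -0.40, 0.25 and 0.22. A second probe of CD68 had 0.42, and with 1 array left out CD68 lay between -1.06 and -0.32.

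**Figure D3:**
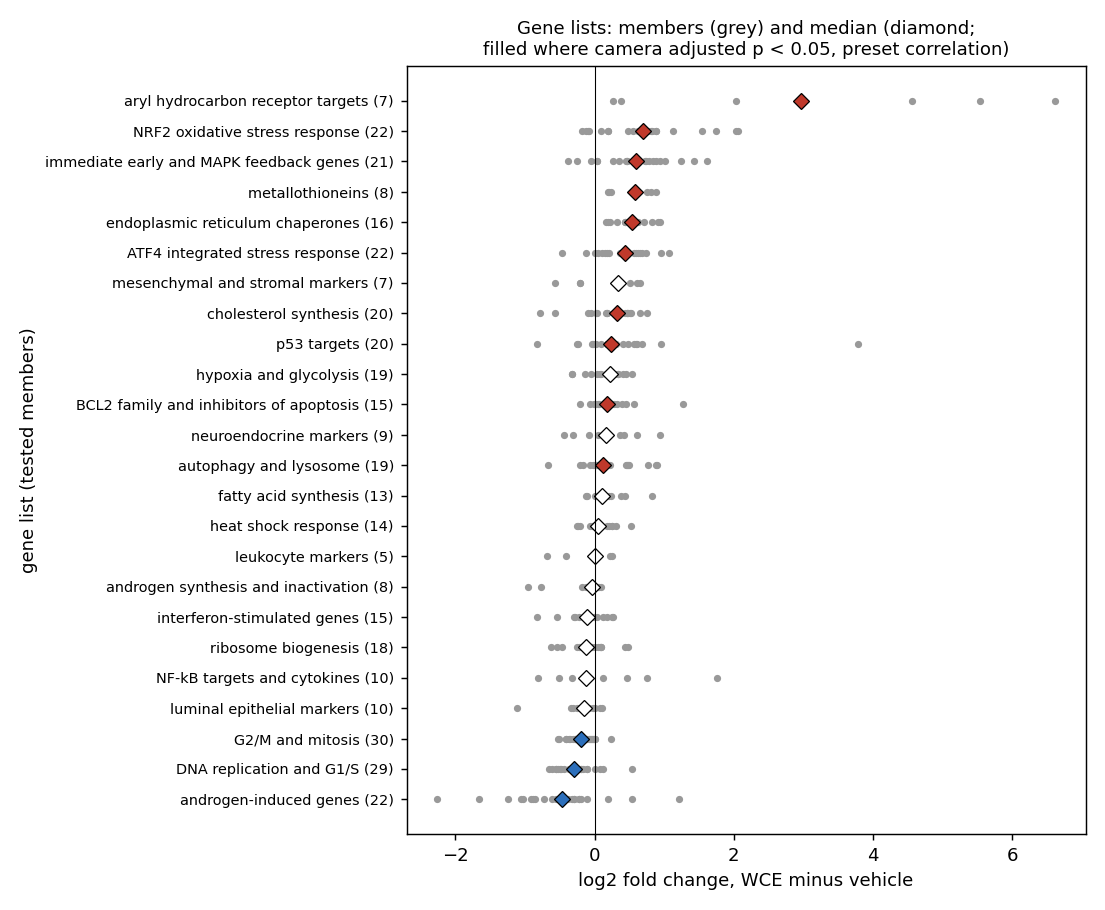
For the 24 lists tested, grey points are the log2 fold changes of the measured members (WCE minus vehicle, x axis) and diamonds the medians, with the number measured in brackets. Diamonds are red or blue for the 10 lists that passed camera upwards and the 3 that passed downwards at the preset correlation, and 0 lists passed with an estimated correlation.

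Across the 24 lists, 13 passed camera at the preset correlation and 9 passed fry, with 8 in both. Some lists share genes, such as NQO1, ME1, SLC7A11, ATF3 and BBC3, so their results are not independent. The 5 lists that passed camera at the preset correlation and not fry were those of ATF4 (fry adjusted p = 0.0536), cholesterol synthesis (0.058), metallothioneins (0.058), the BCL2 family (0.129) and autophagy (0.149). Androgen synthesis passed fry (0.0247) and not camera. Single genes of the lists whose log2 fold changes were over 1.5 times smaller without background correction were SESN2 (0.56), PTGS2 (1.02), DUSP4 (0.84), MT1M (0.43) and IFITM1 (-0.46), the last 2 then not passing. BMF, undetected with vehicle, then had 0.66. This is smaller than its bound of 1.23 on the log2 scale, which holds only with the main background correction. Camera at an estimated correlation passed 0, with unadjusted p-values as low as 0.0142, for the aryl hydrocarbon receptor list. The correlation estimated for that list was -0.162, and those of the androgen-induced and chaperone lists were -0.0346 and -0.0214. These lie below the preset 0.01, so a higher correlation does not account for the loss of these lists. Other lists lay above it, such as NRF2 (0.162) and metallothioneins (0.384). All such estimates rest on the 2 residual degrees of freedom of the fit. Camera then also refers its statistic to these 2 degrees of freedom, which by itself raises the p-values. The count of 0 lists is therefore not evidence that the genes of a list are correlated.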

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

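Added after the data were examined were the crossed pairing and the NRF2 list without NQO1, which it shares with the aryl hydrocarbon receptor list. The count of 229 genes became 388 without background correction, 368 with an offset of 50, 132 with median scaling, 402 with the authors' processed values, 53 without a detection filter, 457 with a trended robust variance, 124 at 2-fold, 69 with limma's treat against 1.2-fold, and 75 to 860 with 1 array left out. The count of 186 probes became 404, 397, 101, 419 and 21 in the first 5 of these, 470 with a trended robust variance, 351 with the strict filter, and 40 to 1107 with 1 array left out. The share of calls that were higher was 62.5%, and 77.3% with median scaling, 79.3% without a filter, 44.8% with the replicate block and 38.4% without WCE replicate 1. Without a filter 20046 genes are adjusted for and the pooled variance is estimated anew: the unfiltered fit adjusted over the 12136 genes alone gave 140 genes, and the filtered fit adjusted over 20046 gave 125. For the other settings the cause was not tested.

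The replicate numbers mark no shared day or batch in the labels, and same-numbered arrays deviated from their group means with a correlation of -0.159 across genes. The replicate block gave 745 genes, 334 higher and 411 lower, and 1188 probes, and the crossed pairing 167 genes. With the block, the adjusted p of named genes followed the size of the change whatever their spread. CD68 (-0.69, WCE SD 0.52) had 0.0380 (limma) and PHLDA3 (0.68, WCE SD 0.07) had 0.0429. Its calls thus act as a cut-off on fold change. A pass with the block, counted here among the other settings, is weak evidence. Among the lists, the block ended the call of autophagy and lysosome genes (adjusted p = 0.0569). The slide as a block was not run, since the slide is not given in the sources used here.

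Of 24 lists, 10 to 15 passed camera in all alternatives with the preset correlation, and 0 with an estimated one. The androgen-induced median lay between -0.51 and -0.30 and passed each time except with an estimated correlation (-0.47, adjusted p = 0.205). Without NQO1 the NRF2 list had a median of 0.68. Medians that changed sign were those of lists that had not passed. They were androgen synthesis (0.0547 with median scaling), NF-kB (0.0269 without a filter, -0.209 to 0.316 with 1 array left out), heat shock (-0.000244 to 0.120) and leukocyte markers (-0.0106 with cyclic loess, -0.0328 without a filter, -0.00306 with the mean of probes, -0.338 to 0.00159 with 1 array left out). Uncalled genes that changed sign were AKR1C3 (0.0115 with median scaling) and, with 1 array left out, LYZ (-0.179 to 0.670), CD2 (-0.338 to 0.788), ARID3B (-0.0222 to 0.250), ULK3 (-0.136 to 0.352) and UGT1A6 (-0.0239 to 0.546). Of 67 named genes that had not passed, 20 passed in at least 1 other setting with all arrays, and HSPA5, EDEM1, UGT2B17, NFKBIA, ATF3, SLC30A1 and CHGB in at least 6. With 1 array left out, 27 of the 67 genes and the medians of 10 of the 11 lists that had not passed moved by over 1.5 times. Of 49 called named genes, 29 passed in all 10 other settings that measured them and 31 with any array left out. Detection above background limits dim genes. Those detected on no array of a group have only bounds. The changes of CYP1A2, ABCG2, CYP2C8, SPATA13, VLDLR, IKBKE, CD2 and UGT1A6, detected on 1 array of a group, rest in part on a signal not above background.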

Other observations

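The genes in this part were chosen after their values were seen. The tests were also chosen after the patterns they concern were seen. For some, limits were written before the tested values were seen. These were the tests on further probes of the genes beside CYP1A1, on the neighbours of other rising genes, and on the brightness and the single arrays behind the androgen-induced list. The limits on single arrays were changed once after most tested values had been seen, then put back as first written.

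Several secretory pathway genes rose with WCE. SEC24D, of the coat of vesicles leaving the endoplasmic reticulum, rose by 1.43 ± 0.17 (log2, SE, n = 2 per group), the retrieval receptor KDELR3 by 0.97 ± 0.17, the translocon subunit SSR3 by 0.92 ± 0.17 and SRPRB, of the signal recognition particle receptor, by 0.80 ± 0.16. A list of genes for translocation into the endoplasmic reticulum and export from it was then written. Without those 4 genes it held 30 tested members, of which 0 passed alone and 29 were higher, with a median log2 fold change of 0.32 (camera p = 3.97e-07, and p = 0.0288 with an estimated correlation, neither adjusted). One member, SEC61B, is also in the chaperone list. This is consistent with a rise of the whole pathway as a hypothesis, on the data that raised it. SEC24D passed with any array left out, while SSR3, KDELR3 and SRPRB lost their calls without either vehicle array, with adjusted p from 0.0923 to 0.27, and without a detection filter (0.0782 to 0.0925). SSR3 and SRPRB did not pass with median scaling (0.0582 and 0.0568), nor SRPRB with cyclic loess (0.057).

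Some genes outside the fixed lists also changed. KLK1 and KLK11, of the kallikrein family, fell 2.03-fold and 2.15-fold, the metalloreductases STEAP1 and STEAP2 2.54-fold and 2.04-fold, and the monoamine oxidase MAOA 2.63-fold. Outside the fixed list only 3 kallikrein genes were tested, too few for a list test of the family. Among those that rose were BMP2 (log2 fold change 1.16), TGFA (1.33, and 0.72 without background correction), EDN1 (0.98), the disulfide isomerase AGR2 (1.96) and ALAS1, the first enzyme of haem synthesis (1.06). Of the genes in this paragraph AGR2 alone passed without a detection filter, and the others had adjusted p from 0.0506 to 0.138. With median scaling KLK1, STEAP2 and EDN1 did not pass (0.052 to 0.0954), nor EDN1 with cyclic loess (0.0647). KLK1, KLK11, STEAP2, EDN1 and ALAS1 each lost their calls with at least 1 of the arrays left out (highest adjusted p 0.0888 to 0.2), as did STEAP1, BMP2 and TGFA (0.056 to 0.105).

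Genes beside CYP1A1 and CYP1A2 rose with them. In the order of the GRCh38.p14 gene table, CLK3 (0.97 ± 0.16, SE), EDC3 (1.80 ± 0.19), CYP1A1, CYP1A2 and CSK (1.25 ± 0.19) are 5 consecutive tested genes past the threshold, while the next on either side, ARID3B (0.11) and CPLX3 (-0.37), did not pass. Of 100 random orders of the tested genes 0 held a run of 5 rising called genes, nor did any of 10000, whose longest run was 4. This argues only against 5 unrelated genes meeting by chance. Random orders also part the related CYP1A1 and CYP1A2, and the run length was taken from this pattern. Chance for CLK3, EDC3 and CSK beside that pair was therefore not tested. A faulty probe is argued against for CLK3, whose further probe had 0.88 ± 0.17, but EDC3 and CSK have 0 further probes, so faulty probes of these genes cannot be told apart from a rise. Whether strongly rising genes in general take their neighbours with them was not settled. Of 20 neighbours of the other named rising genes 1 rose, or 5%, which is between the limits set. It was SSR3 (0.92), among the secretory genes above, which lies beside TIPARP. The other neighbour of TIPARP, CCNL1, had -0.07. A rise of SSR3 with the secretory genes and a rise with its neighbour cannot be told apart here. A rise of the neighbourhood with CYP1A1 may be worth testing, and the calls of CLK3 (adjusted p = 0.144) and CSK (0.0923) are lost without a vehicle array, and without a detection filter (0.0579 and 0.0837).

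The fall of the androgen-induced list was set against a bias of brightness and against 1 poor array. Its median lay at percentile 0 of 10000 random lists matched on mean log2 intensity. After normalization, other genes of such brightness therefore did not share the fall. Quantile normalization holds the typical change of such genes near 0, so the test cannot decide on a bias of brightness in the raw signals. The quality of the RNA on each array was not itself tested. With either WCE array left out the median was at least as far from 0 as -0.456, so the fall did not rest on either alone. The list still passed camera at the preset correlation. With all arrays and an estimated correlation it did not pass (camera adjusted p = 0.205). An effect of WCE on androgen-responsive transcription was not itself tested and stays open, as do other differences between the groups, such as slower growth. Not all related genes moved as lower androgen action alone would have them. The androgen-repressed UGT2B15 fell (-0.96), UGT2B17 had -0.76, and the androgen-induced PTGER4 rose (1.22). The androgen-repressed MET and CCN3 had 0.42 and 0.31 without passing over all genes, and MET passed over its list alone. The rise of the NRF2 list did not rest on NQO1, the gene it shares with the aryl hydrocarbon receptor list: without it the camera adjusted p was 3.08e-09, and it was 0.22 with an estimated correlation, as with NQO1.

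The WCE arrays differed more from each other than the vehicle arrays did, with 140 against 13 genes over 2-fold apart. The difference had a Spearman correlation of -0.000829 across genes with mean intensity. Quantile normalization gives both arrays the same distribution, which holds this correlation near 0. The test therefore cannot decide whether a difference in brightness plays a part. A stronger response in replicate 2 stays open. Over 29 genes of the receptor and androgen-induced lists, its change had a slope on that of replicate 1 of 0.984 ± 0.032 (SE). The slope was 0.916 ± 0.064 without the 3 CYP1 genes and 0.845 ± 0.103 over the 22 androgen-induced genes. Replicate 2 nevertheless had 967 and 813 probes over 2-fold from the vehicle arrays against 443 and 227 for replicate 1. A different share of nuclear-retained RNA stays open too: 14 such transcripts had a median difference, replicate 2 minus replicate 1, of -0.302, at percentile 0.05 of 10000 matched random lists, with a bootstrap SD of 0.129 that is larger than its distance from the limit set, while between the vehicle arrays they had 0.154, at percentile 98.4. That list was written after the most different genes were seen, and AKAP9, with which the median was -0.387, was taken out and the demand on the spread added after that value was seen. The pairs of arrays are too few to rank spreads between groups.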
